A study of Mus musculus with 6 samples.

How the data were processed

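RNA of N18 cells, a mouse neuroblastoma line, was compared on 6 two-channel oligonucleotide arrays of the Agilent whole mouse genome format. Each array carried RNA of cells transfected with an siRNA against Nrsf, the transcription factor gene whose official symbol is Rest, beside RNA of cells transfected with a scrambled siRNA. Per the labels' protocols, total RNA was extracted with Trizol and 1 µg was amplified and labelled with Agilent's linear amplification kit. The siRNA sample was labelled with Cy5 on arrays 1 to 3 and with Cy3 on arrays 4 to 6, and the scrambled sample carried the other dye. The series' design text describes 6 independent, individual samples. It also speaks of overexpression and of human genes, which does not match the sample names and channel labels (siRNA, mouse cells), and the latter were followed. It does not say whether these came from separate transfections, so p-values measure the spread between these samples, part of which may be technical. The siRNA sequences, the transfection time, the scanner, the feature extraction, the background correction and the normalization are not given in the sources used here.

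The values are log2 ratios of the channels of each array that the authors had normalized before they deposited them, for 44290 spots and with 6 columns, each matched to its sample. The log base is not stated and was inferred. A total of 187 spots with no gene name took opposite signs in the 2 dye orientations by more than 0.5 around their mean. They formed groups whose medians lay at -1.68, 0.84, 1.55, 2.18 and 3.41. On a log2 scale these are ratios of 3.20, 1.79, 2.94, 4.52 and 10.6, on a natural log scale 5.35, 2.31, 4.73, 8.81 and 30.2, and on a log10 scale the last would be a ratio of 2567. The log2 scale, usual for array ratios, was taken. A natural log, which would make every fold larger, is not excluded. Spots with a gene name correlated positively between orientations (r across spots of 0.53 to 0.71 over arrays 2 to 6), whereas spots without a name correlated negatively (-0.67 to -0.64). The authors' ratios had thus already been turned to a common direction, and the signs were left as deposited. Which condition is the numerator is not stated. Ratios are given as siRNA over scrambled, which is likely rather than settled: on arrays 1 to 3 this is Cy5 over Cy3 and the order of the sample names, and it sets the treatment over its control. If the ratio ran the other way, every direction would be swapped. Each array's median over spots lay between -0.004 and 0.005, so the arrays were centred as deposited.

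The platform table paired 32089 spots with a gene. Of these, 32042 named 1 gene and 47 named several, and 12201 spots were not listed. Symbols were updated through gene identifiers to those of the GRCm38.p6 gene table, which held 31906 of the identifiers. No coordinates are given, because the build behind the array is not named. A spot entered the tests with a value on all 6 arrays, which held for 43530 spots. Of these, 31866 named 1 gene, and their values were averaged per gene over 19019 genes, of which 10808 had 1 spot. Pairs of spots for a common transcript correlated at 0.47 across 5740 pairs, against 0.013 for shuffled pairs. Signal over background cannot be judged from ratios, and the number of arrays limits the precision.

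Tests used R 4.3.3 with limma 3.58.1 (lmFit and eBayes, with statmod 1.5.0 for the robust alternative). The model held the mean ratio and a dye term for the orientation, with 4 residual degrees of freedom. Adjusted p-values follow Benjamini and Hochberg with a threshold of 0.05, over all spots or all genes. Errors are standard deviations over the 6 arrays and include any dye difference, which the model takes out. For Rest, an exact two-sided sign-flip permutation test over the 6 arrays was added. Rest and 15 gene lists were fixed before the data were examined, and 431 of their 471 distinct genes were measured. The lists were REST targets, REST cofactors, synaptic vesicle, secretory granule, voltage-gated channels, transmitter receptors, neuronal cytoskeleton and adhesion, noradrenergic identity, cell cycle, interferon response, stress and p53 response, glial, mesenchymal and immune markers, and reference genes. They were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated per list, and with fry. Fry's main test asks whether a list moves on balance in a direction, and its mixed test whether members change in either direction.

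The genes named were Rest, the 12 genes with the largest change in each direction among those past the threshold with the same sign on all 6 arrays (RIKEN clones and predicted genes skipped), and up to 4 members per list past the threshold with the largest change. Where no member of a list passed, the member with the smallest p was named. Further members of lists with few calls were named after their values were seen. The procedure was tested on simulated data for the gene comparison of siRNA against scrambled, with 200 of 19019 genes changed in each of 5 rounds and the spread of the real arrays. It recovered 90.8% of the genes changed 1.25-fold, 98.8% of those changed 1.5-fold and 100% of those changed 2-fold or 3-fold, and 5.44% of the calls were false. The simulated noise was independent between genes and equal on all arrays. An array that stands apart and genes that vary together were left out, so these rates need not hold for the real data.

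Alternatives fixed before the data were examined were a model without the dye term, median centring, median centring with scaling, each array left out in turn, robust moderation, an unmoderated one-sample test, spots with at least 2 values per orientation, spots at 0 or constant left out (1300 spots), the first spot per gene, a minimum change of 1.5-fold, and the other list tests. Alternatives chosen after seeing the data were each dye orientation alone, spots of 1 gene only, and averaging by transcript before averaging by gene.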

Results

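Transcript levels were compared between N18 neuroblastoma cells with and without silencing of Rest (also called Nrsf), a zinc finger repressor known for keeping neuronal genes off outside the nervous system. The 6 arrays each set siRNA-treated cells directly against cells given a scrambled siRNA, 3 with the siRNA sample in Cy5 and 3 with it in Cy3. Between 43689 and 43778 of the 44290 spots had a value on each array. Values are log2 ratios of siRNA over scrambled, with the log base inferred from the values (a natural log, which would make each fold larger, is not excluded) and the direction likely from the labels. All directions below would swap if the ratio ran the other way. Over genes, arrays 2 to 6 correlated with each other at 0.54 to 0.82, while array 1 correlated with them at 0.29 to 0.37. The 5th percentile of genes was -0.53 on array 1 and between -0.26 and -0.21 on the other 5.

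The silenced gene itself was lower in siRNA-treated cells on 6 of 6 arrays. Rest had a mean log2 ratio of -0.35 ± 0.13 (SD, n = 6), which is 78.5% of the scrambled level, or a 1.27-fold higher level if the ratio ran the other way. The mean was -0.28 ± 0.10 (SD, n = 3) with the siRNA sample in Cy5 and -0.42 ± 0.13 (SD, n = 3) with it in Cy3. The adjusted p was 0.00353, and the exact sign-flip permutation test gave p = 0.0312, the smallest that 6 arrays allow. The 3 spots of Rest did not move alike. A pair of them fell by 0.44 and 0.55 on the log2 scale, and the other stood at -0.05 with an adjusted p of 0.751. With the first spot per gene in place of the mean, Rest was at -0.05 (adjusted p = 0.742), and on the 3 Cy5 arrays alone its adjusted p was 0.205.

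The first question was which genes changed when Rest was silenced. Of 19019 genes, 2852 passed the threshold, 1119 of them higher and 1733 lower in siRNA-treated cells, and 2378 of the 2852 had the same sign on all 6 arrays. Most changes were small, since 111 genes were higher and 82 lower by at least 1.5-fold. Ppp1cb, a catalytic subunit of protein phosphatase 1, rose 3.63-fold (log2 ratio 1.86 ± 0.31, SD, n = 6), and Bcap29, a membrane protein of the endoplasmic reticulum, rose 3.34-fold (1.74 ± 0.45). Hdac1, a histone deacetylase of REST corepressor complexes, fell 2.94-fold (-1.56 ± 0.29), and Hspd1, the mitochondrial chaperonin, fell 2.74-fold (-1.45 ± 0.11).

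Among the other genes that rose most, Elk3, an ETS family transcription factor, had a log2 ratio of 1.48 ± 0.31, and the imprinted gene Mest had 1.40 ± 0.37. Dazap2 followed with 1.35 ± 0.30. Tle6, of the Groucho family of corepressors, had 1.24 ± 0.47, and the calpain protease Capn5 had 1.21 ± 0.40. Ndfip1, an adaptor of Nedd4-type ubiquitin ligases, rose on each of its 3 spots, with a mean of 1.17 ± 0.40. The SNARE protein gene Vti1b was at 1.11 ± 0.41 and the cytochrome c oxidase subunit gene Cox5b at 1.08 ± 0.29. Ddit4, an inhibitor of mTORC1 signalling, was at 1.07 ± 0.32, and Uap1, an enzyme of UDP-N-acetylglucosamine synthesis, at 1.04 ± 0.36. The adjusted p-values of the 12 genes that rose most lay between 0.000290 for Mest and 0.00424 for Tle6. Of these 12, Ndfip1 alone had several spots. The others, Ppp1cb and Bcap29 among them, rest on 1 spot each, so a faulty spot stays open for them.

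Among the other genes that fell most, Bccip, a BRCA2-interacting protein gene, and Tipin, a replication fork protection factor, each had a log2 ratio of -1.43, with SDs of 0.26 and 0.18. Larp7, an RNA-binding protein gene of the 7SK particle, was at -1.04 ± 0.03, and Gtf2a2, a subunit of the general transcription factor TFIIA, at -1.04 ± 0.11. The small SD of Larp7 comes from averaging 2 spots that went apart on array 1 (-1.52 and -0.53), at -1.18 ± 0.19 (adjusted p = 0.000205) and -0.91 ± 0.19 (adjusted p = 0.000583). Nlrp4c, of the NLR family, was at -1.38 ± 0.12. Limk1, a kinase that acts on cofilin, was at -1.14 ± 0.18, and Pcp4, a calmodulin-binding protein gene, at -1.13 ± 0.28. Cox11, needed to assemble cytochrome c oxidase, fell 2.005-fold. Pphln1 was at -0.99 ± 0.22 and Mid1ip1, a regulator of lipid synthesis, at -0.99 ± 0.22. Among the 12 genes that fell most, 4 had several spots (Hspd1, Larp7, Gtf2a2 and Pphln1), and the weakest of these spots was at -0.65, for Pphln1. The adjusted p-values of the 12 ran from 1.62e-05 for Larp7 to 0.000978 for Pphln1.

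**Figure D1:**
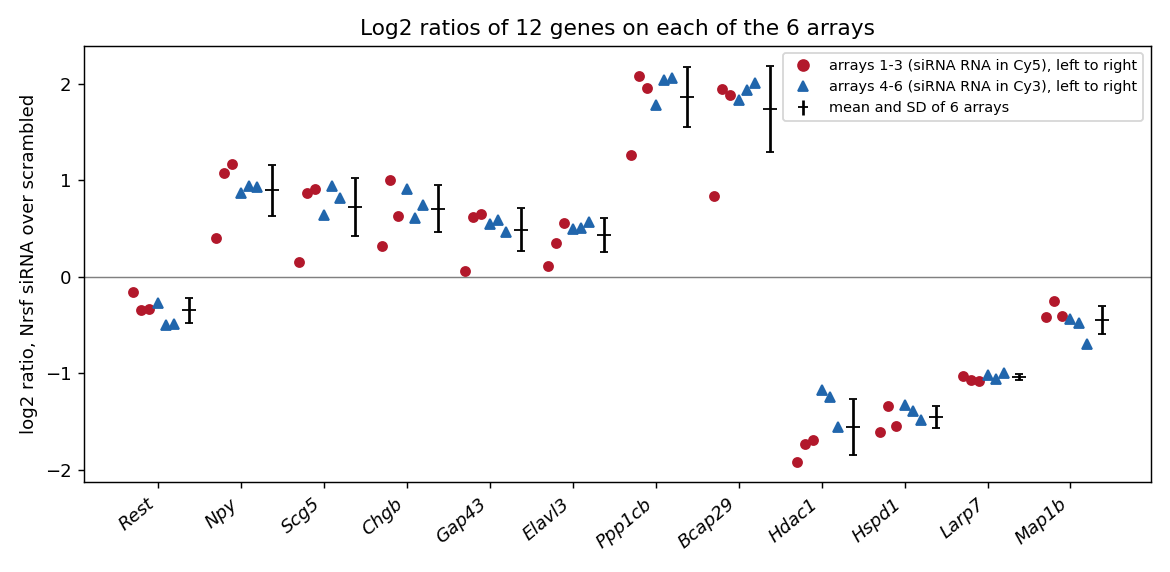
Log2 ratio of Nrsf siRNA over scrambled (vertical axis) for 12 genes on each of the 6 arrays, with circles for arrays 1 to 3, triangles for arrays 4 to 6, and bars for the mean and SD over 6 arrays. Rest lies between -0.50 and -0.16, Hdac1 between -1.93 and -1.18, and array 1 has the lowest value of Bcap29, at 0.84.

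At the level of single spots, 4812 of 43530 passed, 1831 higher and 2981 lower, and 325 and 232 of them by at least 1.5-fold. The counts moved with single arrays. Without array 1, 4921 genes passed, 2603 of them higher. Without array 2, 4, 5 or 6, the number was 1809, 1562, 1116 or 1214. For spots it was 8460 without array 1 and 2830, 1918 or 2146 without array 4, 5 or 6. On the Cy5 arrays alone 9 genes passed. All 2852 genes had the same sign without any single array, and the unmoderated test called 1372 genes.

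**Figure D2:**
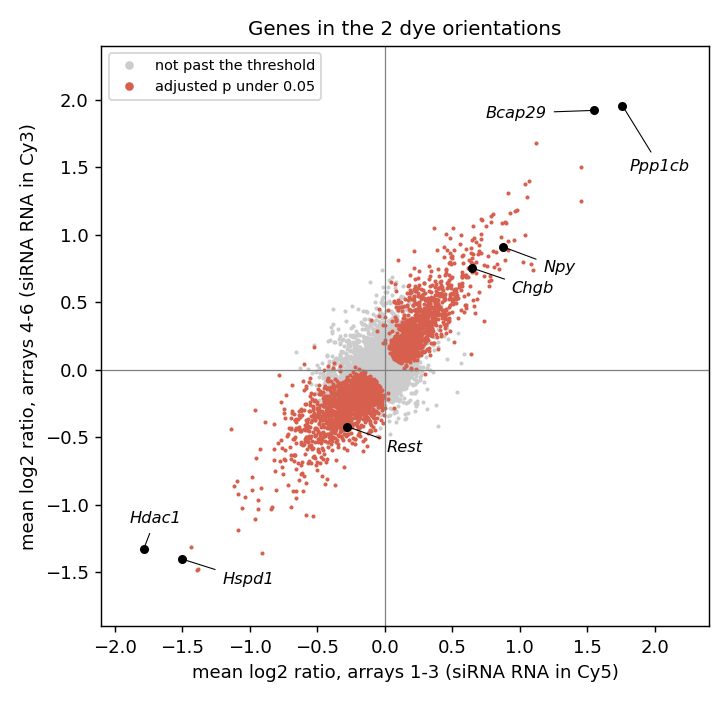
Mean log2 ratio of each of 19019 genes on the 3 arrays with the siRNA sample in Cy5 (horizontal axis) and on the 3 with it in Cy3 (vertical axis), with genes past the threshold in red and 7 named genes in black. Ppp1cb lies at 1.76 and 1.96, Hdac1 at -1.79 and -1.33, and Rest at -0.28 and -0.42.

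The next question was whether genes known to be held down by Rest rose. Of 50 measured genes widely described as carrying a REST binding element, 9 rose and none of them fell past the threshold, with the same 9 when adjusted over the list alone. Chgb, a granin of dense-core granules, rose 1.63-fold (log2 ratio 0.70 ± 0.24, SD, n = 6), with 10 of its 11 spots past the threshold. These 10 were listed for 1 transcript and lay at 0.68 to 0.81, so they are not separate evidence. The spot listed for another transcript was at 0.0055 (adjusted p = 0.962 in limma). Elavl3, a neuronal RNA-binding protein gene, was at 0.43 ± 0.17, the neuronal tubulin Tubb3 at 0.30 ± 0.23 and Disp2 at 0.30 ± 0.09. The remaining 5 were Mapk8ip1 (0.29 ± 0.07), Chga (0.21 ± 0.15), Slc12a5 (0.21 ± 0.14), Scg3 (0.16 ± 0.09) and Cplx1 (0.11 ± 0.06). For the other 41 no change was called, and the list median was 0.016.

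The list was called higher by camera at the preset correlation (adjusted p = 0.00880), but not with an estimated correlation (adjusted p = 0.250). The estimate was -0.0074, below the preset 0.01, so joint variation of the members does not account for that miss. The unadjusted p by camera with the estimated correlation was 0.0167, so the list missed the threshold only after adjustment over the lists. Without array 1 camera did not call the list either (adjusted p = 0.137), and 10 members were higher and 0 lower. Without array 2, 3, 4, 5 or 6, 4, 4, 5, 4 or 4 members were higher and 0 lower. Fry called it higher (adjusted p = 0.00157). Spots of Elavl3 disagreed, at -0.03 and 0.89, and so did those of Disp2, at 0.001 and 0.59. Tubb3 was at -0.15 on array 1 and between 0.33 and 0.46 on the other arrays.

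The REST cofactor list held genes of the complexes that REST recruits and of regulators of REST protein. Of 24 measured, 7 fell and 1 rose (8 and 1 when adjusted over the list alone). The count was 9 lower and 5 higher without array 1, and 4 or 5 lower and 1 higher without any other array. Besides Hdac1, Ctdsp2, a small C-terminal domain phosphatase, fell by 0.40 ± 0.21 on the log2 scale, and Smarca4, the ATPase of the BAF chromatin remodelling complex, fell by 0.28 ± 0.06. The spots of Smarca4 disagreed, at -0.41, -0.43 and -0.0005 (adjusted p = 0.997 in limma for the last). Zfp217 (-0.28 ± 0.08), Smarce1 (-0.24 ± 0.11), Cbx5 (-0.10 ± 0.07) and Phf21a (-0.08 ± 0.03) also fell. Rcor1, which encodes the corepressor CoREST, rose, with a mean of 0.46 ± 0.14 over spots that ranged from 0.003 to 1.11. Camera called the list lower (adjusted p = 0.0177) at the preset correlation, not with an estimated correlation (adjusted p = 0.535) or without array 1 (adjusted p = 0.155). Its median was -0.20 on array 1 and between -0.069 and -0.028 on the others.

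Granule and neuropeptide genes held the largest rises among the neuronal lists. Of 25 secretory granule genes, 5 rose and 1 fell, with equal counts when adjusted over the list alone. Neuropeptide Y (Npy) rose 1.86-fold (0.89 ± 0.27, SD, n = 6) and Scg5, a chaperone of prohormone processing, 1.65-fold (0.72 ± 0.30). The others that rose, Chgb, Chga and Scg3, are also on the list of REST targets. Cartpt, a neuropeptide gene, fell by 0.26 ± 0.13. Camera did not call this list (adjusted p = 0.0702, and adjusted p = 0.357 with an estimated correlation), and fry did (adjusted p = 0.0286). In the model without the dye term camera called it too (adjusted p = 0.0435). Without array 1, 6 genes were higher, and without any other array 3 were.

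Synaptic, channel and receptor genes that changed were small in number and mostly higher. For scale, 1119 of all 19019 genes rose and 1733 fell. Of 48 synaptic vesicle genes, 5 rose and 0 fell with all arrays, but 0 rose without array 3, 5 or 6, 1 without array 2 or 4, and 7 without array 1. The 5 were Sypl (0.30 ± 0.19), the complexins Cplx2 (0.20 ± 0.11) and Cplx1, the calcium sensor Syt1 (0.13 ± 0.07) and Rab3c (0.08 ± 0.04). None of these was past the threshold when adjusted over the list alone, where 0 genes passed and 12 had an unadjusted p under 0.05 in limma. The 5 spots of Syt1 ranged from -0.06 to 0.31, and 1 of them passed, as did 1 of the 3 spots of Sypl. Of 48 voltage-gated channel genes, 4 rose and 1 fell, as when adjusted over the list alone. The sodium channel subunit Scn3b was at 0.46 ± 0.22, the potassium channel Kcnh2 at 0.30 ± 0.14, and the auxiliary subunits Kcnab2 and Kcnab1 at 0.15 ± 0.07 and 0.14 ± 0.06, while Kcnn2 was at -0.11 ± 0.04. The spots of Scn3b lay at 0.03 and 0.89, and those of Kcnab1 at 0.02, 0.04 and 0.36. Of 51 transmitter receptor genes, 3 rose and 0 fell, also when adjusted over the list alone. Without array 4, 5 or 6, 2, 1 or 1 channel genes rose, and without array 2, 5 or 6, 0 receptor genes did. The receptor genes were the serotonin-gated channel Htr3a (0.51 ± 0.25), the nicotinic subunit Chrna3 (0.34 ± 0.17) and the GABA receptor subunit Gabrg1 (0.17 ± 0.09). Adjusted p-values of camera for the 3 lists were 0.0729, 0.122 and 0.209. Without array 2 camera called the synaptic vesicle list higher (adjusted p = 0.0424). Fry called the synaptic vesicle and channel lists higher (adjusted p = 0.00291 and 0.0347), not the receptor list (0.187). With an estimated correlation camera gave adjusted p-values of 0.357, 0.484 and 0.536.

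Neuronal cytoskeleton and adhesion genes went in both directions. Of 42 measured, 7 rose and 4 fell (8 and 4 when adjusted over the list alone). Gap43, a growth cone protein gene, was at 0.49 ± 0.22, and the RNA-binding protein gene Elavl2 at 0.45 ± 0.14. The microtubule-associated Map1b fell by 0.45 ± 0.14, and the others that fell were Dpysl2 (-0.30 ± 0.12), Stmn1 (-0.25 ± 0.11) and Nlgn2 (-0.13 ± 0.06). The spots of Map1b lay at -0.17 and -0.72, and those of Elavl2 at 0.14 and 0.76. Camera did not call the list (adjusted p = 0.209), and fry gave an adjusted p of 0.0486. With an estimated correlation the adjusted p was 0.473. The count was 11 higher and 4 lower without array 1, 3 and 2 without array 5, and 4 and 3 without array 6.

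In the list of noradrenergic identity, 3 of 21 genes rose and 2 fell (5 and 2 when adjusted over the list alone). The homeobox gene Phox2a was at 0.44 ± 0.22, Hand2 at 0.20 ± 0.12 and the neurotrophin receptor Ngfr at 0.19 ± 0.11. The transcription factor Gata3 was at -0.51 ± 0.15 and Maoa, which degrades monoamines, at -0.20 ± 0.11. The adjusted p was 0.344 by camera and 0.212 by fry. Without a single array the number that rose lay between 0 (array 4 or 5) and 4 (array 1).

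Cell cycle genes were more often lower than higher. Of 40 measured, 13 fell and 3 rose (18 and 4 when adjusted over the list alone). The spindle checkpoint gene Mad2l1 fell by 0.54 ± 0.17 on the log2 scale, the replicative helicase subunit Mcm7 by 0.50 ± 0.23 and the kinase Cdk4 by 0.47 ± 0.21. E2f2, a transcription factor of the cell cycle, rose 1.64-fold (0.72 ± 0.34), and the cyclins Ccne1 (0.32 ± 0.22) and Ccnd3 (0.21 ± 0.13) rose too. The list median was -0.14 over all arrays. It was -0.37 on array 1 and between -0.074 and -0.035 on the other 5. Camera called the list lower (adjusted p = 0.00129), not with an estimated correlation (adjusted p = 0.536), and not without array 1 (adjusted p = 0.137), where 18 members were lower and 7 higher. Without array 5 or 6, 8 were lower and 0 higher. Fry did not call it (adjusted p = 0.0984), and its mixed test passed (adjusted p = 0.000462), as it did for 12 of the 15 lists.

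Stress and interferon genes changed in part and in both directions. Of 26 stress and p53 response genes, 6 rose and 3 fell (6 and 4 when adjusted over the list alone). Gadd45b, a stress-induced gene, rose 1.79-fold (0.84 ± 0.37), heme oxygenase Hmox1 rose 1.73-fold (0.79 ± 0.42) and Xbp1, of the unfolded protein response, was at 0.45 ± 0.20. The transcription factor Atf5 was at -0.59 ± 0.29. Of 34 interferon response genes, 2 rose and 2 fell, as when adjusted over the list alone. Psmb8, a subunit of the immunoproteasome, rose 1.57-fold (0.65 ± 0.30) and Ifi35 was at 0.32 ± 0.21, while the chemokine Ccl5 was at -0.21 ± 0.17 and Stat2, which carries the interferon signal, at -0.19 ± 0.04. Without array 1 the stress list had 9 higher and 4 lower and the interferon list 7 and 4. Without array 5 they had 1 and 2, and 0 and 1. The adjusted p was 0.369 by camera and 0.276 by fry for the stress list, and 0.815 and 0.817 for the interferon list. The median and the mean of the interferon list differed in sign, at -0.0003 and 0.024, and so did those of the stress list, at -0.006 and 0.055.

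Markers of other cell types hardly moved. None of 16 glial or 8 immune markers passed the threshold in limma, also when adjusted over the list alone, and 1 and 0 of them had an unadjusted p under 0.05. The smallest p-values belonged to S100b, at 0.09 ± 0.11, and to the complement gene C1qa, at -0.04 ± 0.05. Of 22 mesenchymal markers, S100a4 rose (0.24 ± 0.07), also when adjusted over the list alone. Its spots disagreed, at 0.47 and 0.01. Camera gave adjusted p-values of 0.377, 0.815 and 0.209 for the glial, immune and mesenchymal lists. By fry, which tests for a shift on balance, the glial (adjusted p = 0.0286) and mesenchymal lists (0.00157) were higher, with medians of 0.014 and 0.012, and the immune list was not called (0.652). With an estimated correlation the adjusted p was 0.536 for the glial and 0.473 for the mesenchymal list. Without array 1, 1 glial marker rose. Of 13 genes often used as references, the transferrin receptor gene Tfrc fell by 0.24 ± 0.12, likewise when adjusted over the list alone, with an adjusted p for the list of 0.634 by camera and 0.613 by fry. Without array 1, 2 reference genes were higher and 2 lower, and without array 2, 3 or 6 none of them was called. The reference genes' median was -0.19 on array 1 and between -0.041 and 0.073 on the others.

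**Figure D3:**
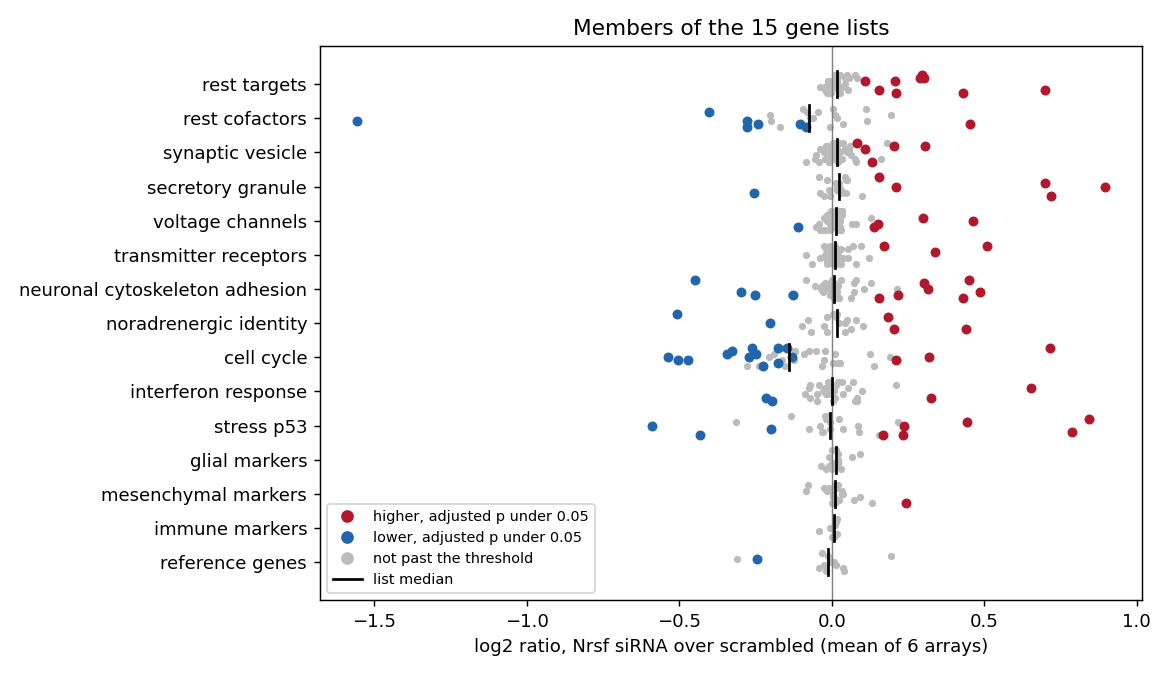
Mean log2 ratio of Nrsf siRNA over scrambled over 6 arrays (horizontal axis) for each measured member of the 15 lists, in red or blue where past the threshold, with the list median as a black line. Cell cycle genes have a median of -0.14 and REST cofactors of -0.076, while the other medians lie between -0.012 and 0.024.

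The swap of dyes allowed a test of the dye itself, and few spots of named genes differed between orientations. A dye difference was called for 243 of 43530 spots, 175 with the higher ratio in the Cy5 orientation and 68 with the lower, a balance set by spots without a gene name. Of these, 198 spots had no gene name, 182 of them among the 187 unnamed spots with opposite signs in the 2 orientations, and 45 named 1 gene, 14 of these higher and 31 lower. For Rest the adjusted p of the dye term was 0.609, and for Hdac1, which was at -1.79 with the siRNA sample in Cy5 and at -1.33 with it in Cy3, it was 0.429. Among the genes named, none had a called dye difference. The number called was 1997 without array 1 and 148, 86, 63, 0 and 0 without arrays 2 to 6 in turn.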

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

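The tests of array 1 by the share of change kept, of faulty spots, of the Rest spots and of correlated cell cycle members, and the counts over other splits of the arrays, were chosen after the results were seen. A sample far from the other 5 was looked for in 86 results, the 69 named genes, 15 list medians and 2 percentiles of all genes. Chance alone would give about 4.3. There were 23, of which 18 concerned array 1.

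Array 1 stood apart for several of the genes that rose most. Its log2 ratio was 1.26 for Ppp1cb (1.78 to 2.08 on the others), 0.84 for Bcap29 (1.83 to 2.01), 0.30 for Tle6 (1.33 to 1.58), 0.42 for Capn5 (1.23 to 1.49), 0.41 for Ndfip1 (1.06 to 1.43), 0.29 for Vti1b (1.21 to 1.35) and 0.51 for Cox5b (1.05 to 1.29). It was likewise lower for Tubb3 (-0.15), Rcor1 (0.19), Syt1 (-0.003), Kcnab2 (0.014), Gap43 (0.057) and Ifi35 (-0.076). Mcm7 was at -0.95 on array 1 (-0.53 to -0.33 on the others), and Atf5, which fell elsewhere, at -0.031. The medians of the cell cycle list (-0.37) and of the REST cofactors (-0.20), and the 5th percentile of genes (-0.53), were lowest there too.

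The tables argue against 2 explanations of this as the sole cause. Weaker silencing in sample 1, or a narrower ratio scale on array 1 for every spot, would shrink rises and falls alike. The 5 groups of unnamed spots with opposite signs in the dye orientations did shrink on array 1, in both directions. Their medians there were 0.283 to 0.531 of the mean of arrays 2 and 3, which goes with a narrower scale for those spots. Rest itself fell least on array 1 (-0.16, against -0.50 to -0.27 on the others), which goes with weaker silencing, but genes called without array 1 and changed at least 1.5-fold kept a median share of 0.217 of the other arrays' change on array 1 if they rose (175 genes), but 1.09 if they fell (68 genes). A bias on array 1 that goes with transcript abundance may account for it and stays open: ribosomal protein genes had a median of -0.0975 there, below the lowest of the others (-0.0015) by slightly less than the 0.1 set beforehand, and intensities were not analysed here. Medians on array 1 were lower for proteasome (-0.43), mitochondrial ribosomal (-0.38) and oxidative phosphorylation genes (-0.33). Abundance was not measured, so whether these values go against such a bias cannot be told. A mixture of these causes, weaker silencing included, or a real difference of sample 1, was not tested.

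Falls larger than that of Rest are the next pattern, since 19 named genes fell by more than the silenced gene did. Among the 12 that fell most, a faulty spot stays open for the 8 genes with 1 spot, Hdac1 among them, and for the 4 with several, whose weakest spots had a median log2 ratio of -0.83, since genes were picked by their mean over spots and in 3 of the 4 a spot at 0 would have needed another below every spot measured. The largest fall of a Rest spot was -0.55 ± 0.09 and the smallest of the 12 falls -0.99, so no Rest spot reached them. Because the 12 were picked as the largest falls, this does not decide whether an unresponsive Rest spot hides an equal fall. For the other 7 an unresponsive Rest spot may account for the pattern. Of these, 6 fell less than the Rest spot with the largest fall, and all 7 lay within 1 SD of it or above. This sets a single spot of Rest against gene means over spots. Among those with several spots, the lowest spot was at -0.72 for Map1b, -0.57 for Mad2l1 and -0.46 for Ctdsp2. Effects of the siRNA on transcripts other than Rest may also be involved and were not tested, because its sequence is not given in the sources used here.

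For the lower cell cycle list, dye bias is argued against: the list median was -0.15 on the Cy5 arrays and -0.081 on the Cy3 arrays. The size of the Cy5 value leans on array 1 (-0.37), since arrays 2 and 3 were at -0.039 and -0.0645. The sign does not, as the median was below 0 on all 6 arrays. Members that vary together between arrays stay open as an explanation of the call. Their estimated correlation was 0.577, but the test with it passed none of the 15 lists, REST targets (-0.0074) included, so that its miss does not decide. Whether array 1 carries the shift stays open, because the median over arrays 2 to 6 was -0.074, with the single arrays between -0.074 and -0.035. No biological explanation of the shift was tested.

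On other arrays, Ddit4 was at 1.71 on array 4 (0.80 to 1.08 elsewhere) and Pphln1 at -0.57 on array 4 (-1.17 to -0.98). Limk1 was at -0.78 on array 3 (-1.24 to -1.14) and Ccl5 at 0.12 on array 3 (-0.37 to -0.22). The secretory granule median was 0.039 on array 2 (0.016 to 0.025). Outside the gene comparisons, 187 spots without a gene name had opposite signs in the dye orientations, against 1 spot of a named gene. The medians of their 5 groups on array 1 were between 0.283 and 0.531 of the mean of those on arrays 2 and 3.

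The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2852 genes, 4812 spots and 243 spots for the dye, and the highest of the other splits called 0 of each, so that 1 of 10 splits reached each count. For the lists the real split called 3 and another called 5, and 4 of 10 splits called as many. In the model without a dye term the signs of the 6 arrays can be set in 32 ways, and 1 of them, the real signs, called 2810 genes. The highest of the others called 982, in the pattern with only array 1 turned. The signs had been left as deposited because spots with a gene name correlated positively between orientations. Patterns that turn some arrays against the rest cancel such a shared direction, so this count cannot decide about chance.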

How the results depend on the processing

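Each dye orientation alone, spots of 1 gene and averaging by transcript were chosen after seeing the data. Median centring, with or without scaling, changed no call of a named gene and no list call, and all 69 named genes kept their direction in every setting except Elavl3, at -0.030 with the first spot per gene, which is its unresponsive spot. Over the alternatives, named genes kept their side of the threshold in 867 comparisons and lost the call in 167, of which 61 were on the Cy5 arrays alone. With an array left out, changed spots ranged from 1918 to 8460, changed genes from 1116 to 4921, spots with a dye difference from 0 to 1997 and lists called from 0 to 4. The adjusted p of the list test then ranged from 0.00281 to 0.137 for REST targets, 0.00755 to 0.155 for REST cofactors and 3.4e-05 to 0.137 for cell cycle, each highest without array 1. The unmoderated test called 1493 spots and 1372 genes, and a minimum of 1.5-fold left 557 and 193. The Cy5 arrays alone called 0 spots (limma) and 9 genes, and the Cy3 arrays alone 7924 spots and 4262 genes. Rest was at -0.054 with the first spot per gene and at -0.28 on the Cy5 arrays alone, without a call. With an estimated correlation 0 lists passed (REST targets 0.250, REST cofactors 0.535, cell cycle 0.536), and by fry 8, not cell cycle (0.0984). REST targets missed the threshold with the first spot per gene (0.0536). Lists without a call changed direction for interferon genes by fry (0.817) and without array 4 (0.985, range 0.734 to 0.985), and for reference genes without array 1 (0.759, range 0.243 to 0.759). Fewer arrays leave fewer degrees of freedom. For the other changes the cause was not tested. Signal over background was not analysed here, so its limits are unknown.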

Other observations

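The gene families in this part were chosen by symbol after the named genes had been seen. Their counts come from the same fit over 19019 genes, of which 1733 fell and 1119 rose. Of 71 subunits of RNA polymerases and general transcription factors, Gtf2a2 among them, 20 fell and 1 rose, or 28 and 6 without array 1. Polr2c, a subunit of RNA polymerase II, had a log2 ratio of -0.89 ± 0.13 (SD, n = 6), Polr1c -0.67 ± 0.35, Gtf2f2 -0.55 ± 0.07 and Gtf2f1 -0.55 ± 0.21. Of 43 proteasome genes 14 fell, among them Psma6 (-0.63 ± 0.18) and Psmc3 (-0.51 ± 0.09), and the 1 that rose with all arrays was the immunoproteasome subunit Psmb8. Without array 1, 19 proteasome genes fell and 7 rose. Among 76 chaperone genes, 15 fell and 3 rose (21 and 8 without array 1), with the mitochondrial Hspa9 (-0.58 ± 0.13) beside Hspd1. Zinc finger genes with symbols in Zfp had 53 lower and 7 higher of 324 (68 and 21 without array 1), led by Zfp985 (-0.83 ± 0.32) and Zfp987 (-0.81 ± 0.37).

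Of 63 translation factor genes 17 fell and 4 rose (22 and 6 without array 1), with Eif5b at -0.56 ± 0.13, and of 35 tRNA synthetase genes 7 fell and 0 rose (11 and 1). Among 78 mitochondrial ribosomal protein genes, 19 fell and 1 rose, but 28 fell and 15 rose without array 1. Cytosolic ribosomal protein genes had 8 higher and 3 lower of 75 (21 and 7 without array 1), with Rpl13 at -0.67 ± 0.17 and Rps20 at 0.35 ± 0.18. Of 98 genes of oxidative phosphorylation 8 rose and 5 fell (24 and 9 without array 1), and of 23 dual-specificity phosphatase genes 4 rose and 3 fell (7 and 4), with Dusp2 at 0.94 ± 0.59. Leaving out another array lowered most counts. Without array 5, for example, 9 transcription machinery, 7 proteasome, 4 mitochondrial ribosomal and 22 zinc finger genes fell. These counts were chosen after seeing the data. The family medians kept their sign under median centring and scaling. For oxidative phosphorylation the median was -0.026 with all arrays and 0.038 without array 1.

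The hypothesis that symbol families move together was tested over 10 families. Camera called 7 of them lower at the preset correlation, with adjusted p-values from 4.76e-08 for the transcription machinery to 0.00304 for chaperones, and none with an estimated correlation, where 0 families passed and the adjusted p lay between 0.560 and 0.904. Without array 1 camera called 9, with ribosomal proteins (adjusted p = 0.0113) and oxidative phosphorylation (0.0284) higher, and the p of mitochondrial ribosomal proteins moved from 1.37e-05 to 0.0113. Fry called 2, the transcription machinery (adjusted p = 0.0424) and zinc finger genes (0.0179). On array 1 the family medians were lowest for proteasome genes (-0.43), mitochondrial ribosomal proteins (-0.38) and oxidative phosphorylation (-0.33), against -0.11 to -0.03, -0.086 to 0.04 and -0.023 to 0.08 on the other arrays. Estimated correlations between members reached 0.733 for mitochondrial ribosomal proteins, 0.598 for proteasome genes and 0.551 for oxidative phosphorylation. Zinc finger genes (0.020) and chaperones (0.141) missed the threshold as well, so strong joint variation does not account for every miss. The 0 calls had been set beforehand to count against the hypothesis. By that rule they do, but the test also misses lists for a reason other than joint variation. The REST target list, with an estimated correlation of -0.0074, went from an adjusted p of 0.00880 to 0.250 in it. The unadjusted p of that list by camera there was 0.0167, so it missed the threshold only after adjustment over the lists. The misses therefore do not decide the question. Medians were below 0 on all 6 arrays for the transcription machinery and zinc finger genes, which fry called. Such medians were also found for proteasome, tRNA synthetase, translation factor and chaperone genes, each with an adjusted p of 0.0503 by fry. That lies close to 0.0424 for the transcription machinery, so these values do not set the called families apart. All families were chosen after the named genes had been seen. A shift with the siRNA and joint variation between arrays cannot be told apart with 6 arrays.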
